A study of Mus musculus with 24 samples.

How the data were processed

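RNA sequencing was done on mouse pancreatic islets from animals aged 3 to 4 months on a mixed genetic background, per the labels' protocols. Islets were cultured, picked by hand and lysed, and RNA was purified on columns with DNase treatment, per the labels' protocols. Libraries were prepared and sequenced by standard Illumina methods, per the labels' protocols. The values are RPKM (reads per gene, scaled to the length of the gene and the reads of the library), as deposited by the authors. The genome build was mm9, per the submitters' processing notes. The aligner, the read counter and the gene annotation are not given in the sources used here.

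The table holds 28059 genes by NCBI Gene number and 24 library columns. A library was assigned to a group by the sample number in its title, and 22 columns were used. In 1 case, a sample number stands in 2 titles and 1 column begins no title, so 2 columns could not be placed and enter no step. This leaves 3 replicates in the set 1 control and set 1 Cop1 deletion groups and 4 in each other group. The design text counts 5 biological replicates per genotype and does not say how replicates relate to mice or cultures. Symbols came from the GRCm38.p6 annotation by NCBI Gene number, which matched 24998 genes and left 3061 without a symbol. Of the genes tested, 1075 had no symbol. Chromosomes and distances refer to GRCm38.p6, which is not the build of the reads, so no coordinates are given.

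Read depth was derived from the table. Below 0.3 RPKM, most values of a library are whole multiples of a step that falls as the number of reads rises. Over 4512 low genes, 88.2% to 89.5% of the values in set 1 and 89.7% to 91.6% in set 2 lay within 0.01 of a whole multiple. Set against the deepest library, the depth was 0.331 to 0.526 in set 1 and 0.758 to 1 in set 2. The number of reads itself is unknown, and the step of a gene depends on its length, so no model for read counts and no counting interval was used.

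Genes with at least 1 RPKM in at least 4 libraries were tested, which kept 14342 genes. Values were taken as log2(RPKM + 0.5), so that log2 fold changes of genes below a few RPKM are understated. limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust variance estimation, fitted 1 mean for each of the 6 groups. The 9 comparisons were 2-sided contrasts of these means, and each stays within a set or is a mean or difference of such contrasts. An adjusted p is a Benjamini-Hochberg value from limma over all genes tested, with a threshold of 0.05, and a gene below it is called. Tables were handled with the R package data.table, version 1.17.8. The test was tried on simulated libraries with the same genes and group sizes. Each value was drawn from a normal distribution with the mean and within-group SD of its gene, and 200 genes were changed by a known factor. The draws were independent, without correlated genes, outlying libraries or a difference between sets, so the rates hold for simpler data than these libraries. In the 2-set comparison the test called 82.1% of genes changed 1.5-fold, 94% of those changed 2-fold and 0.12% of unchanged genes. In the 4 comparisons within a set that were tried, it called 65.7% to 74.6%, 86.6% to 89.6% and 0.03% to 0.08%.

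The 27 gene lists were fixed before the data were examined. For each list, members were counted as called over all genes and with adjustment over the list alone. The list as a whole was tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists of a comparison. Named genes were chosen by a rule. The targeted genes are always named. From each list, up to 4 called members with the smallest adjusted p can be named, or up to 2 members with the highest mean RPKM where none is called. The 10 genes with the largest log2 fold change in each direction can be named if they are called, reach a mean of 1 RPKM in a group compared and have no overlap between the groups. Any other gene is said to be chosen after its values were seen. Esr1, Hspa1a, Dnajb1, C1qb and C1qc were chosen in that way where the rule does not name them. 1 gene that this rule would name is not reported here.

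The return toward control was measured across the sets, so that list and test share no library. In each library, the genes called after Cop1 deletion in the other set were averaged, with falling genes counted negative. The return is the share of the difference between Cop1 deletion and control that is absent in the Etv deletion libraries, tested by exact permutation of the library labels, 2-sided. Overlaps between lists are given beside the number expected if the lists were independent. Libraries were also regrouped into all other splits of the same sizes, up to 100, and each split was tested in the same way.

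Alternatives covered the pseudocount, the filter, the scaling, the fit, library weights, a 2-fold minimum and leaving out each library in turn. A further 3 alternatives were chosen after seeing the data: the level of Y-linked genes as a covariate, set 2 libraries with at least 1 RPKM of Xist only, and the level of acinar markers as a covariate. The fit without set 1 control replicate 2, among the planned removals, was singled out after its Esr1 value was seen. Their effect is given in the closing section.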

Results

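Gene expression was measured by RNA sequencing in mouse islets after deletion of Cop1 in β cells. COP1 is an E3 ubiquitin ligase that marks transcription factors, among them the PEA3 group of ETS factors (ETV1, ETV4 and ETV5), for degradation. Deletion was driven by Pdx1.CreERT2, a tamoxifen-activated Cre recombinase fused to an estrogen receptor domain. The sample numbers divide the libraries into 2 sets. Set 1 held 3 control libraries (floxed Cop1 without Cre), 3 Cop1 deletion libraries and 4 libraries labelled Cop1 Etv1 Etv4 Etv5 deletion, below called the Etv1/4/5 libraries. Set 2 held 4 control libraries, 4 Cop1 deletion libraries and 4 libraries labelled Cop1 Etv4 Etv5 deletion with 1 Etv4 allele left, below called the Etv4/5 libraries. The design asks what loss of Cop1 changes in islets and which of these changes need the ETV factors.

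Total RPKM was 569486 to 664207 in the 10 libraries of set 1 and 524289 to 682560 in the 12 of set 2. Between 12995 and 13595 genes reached 1 RPKM. Depth relative to the deepest library had a median of 0.382 in set 1 and 0.878 in set 2, so low values are coarser in set 1, and the number of reads is unknown. Rank correlation had a median of 0.988 within groups (30 pairs, lowest 0.9372), 0.979 between groups of the same set (81 pairs) and 0.9 across sets (120 pairs). Ins1 and Ins2 together made up 38.9% to 40.7% of RPKM in set 1 controls, 31.5% to 34.5% in set 1 Cop1 deletion and 35.8% to 41.1% in the Etv1/4/5 libraries. In set 2 the shares were 26.9% to 30.7%, 21% to 27.1% and 25.8% to 28.9% in the same order. Xist, the transcript of the inactive X chromosome, was present in all 4 set 2 controls but in only 2 of 4 Cop1 deletion and 2 of 4 Etv4/5 libraries. The other 2 libraries of each of these groups had Y-linked transcripts. In set 1 each group held Y-linked transcripts and Xist, and 3 libraries had both.

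Cop1 (NCBI Gene 26374) was lower in every library labelled with Cop1 deletion than in every control of its set. It was 1.44 ± 0.19 RPKM (SD, n = 3) in set 1 controls, 1.04 ± 0.079 (n = 3) after Cop1 deletion and 0.893 ± 0.14 (n = 4) in the Etv1/4/5 libraries. The libraries ran from 1.22 to 1.55, from 0.984 to 1.13 and from 0.719 to 1.04. In set 2 it was 1.64 ± 0.19 in controls, 0.875 ± 0.078 after Cop1 deletion and 0.816 ± 0.045 in the Etv4/5 libraries (n = 4 each). Those libraries ran from 1.43 to 1.87, from 0.763 to 0.934 and from 0.77 to 0.856. A value per gene does not separate reads of the deleted part from reads of the rest.

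Etv4 (NCBI Gene 18612) did not follow its label. In the Etv1/4/5 libraries, labelled as lacking both Etv4 alleles, it was 1.26 ± 0.3 RPKM (n = 4), against 0.0728 ± 0.04 (n = 3) in control and 0.0646 ± 0.012 (n = 3) after Cop1 deletion. It was 0.532 ± 0.15, 0.947 ± 0.49 and 0.911 ± 0.19 in set 2 control, Cop1 deletion and Etv4/5 libraries (n = 4 each). Etv1 (NCBI Gene 14009) was 6.53 ± 0.78, 4.72 ± 0.43 and 5.3 ± 0.31 in set 1 and 5.46 ± 0.69, 4.14 ± 1.6 and 5.87 ± 0.86 in set 2, in the same order, and was called in no comparison. Etv5 (NCBI Gene 104156) was 4.94 ± 3.2, 2.8 ± 0.68 and 3.69 ± 1 in set 1 and 5.39 ± 1.8, 2.14 ± 0.64 and 1.56 ± 0.2 in set 2. The values per gene therefore do not check the loss of the Etv genes, which rests on the labels alone in each comparison with these libraries. Etv4 did set the Etv1/4/5 libraries apart from the rest of set 1, but against the direction of the label.

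Esr1, the estrogen receptor gene whose ligand-binding domain is part of CreERT2 fusions, separated the libraries labelled with Cre from controls with 1 exception. It was 0.133 ± 0.065 RPKM in set 2 controls, 60.1 ± 17 after Cop1 deletion and 90.1 ± 12 in the Etv4/5 libraries (n = 4 each). In set 1 it was 108 ± 3.2 after Cop1 deletion (n = 3) and 66.7 ± 12 in the Etv1/4/5 libraries (n = 4). The library labelled set 1 control replicate 2 had 99.1 RPKM, and the other 2 controls had 0.169 and 0.191.

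**Figure D1:**
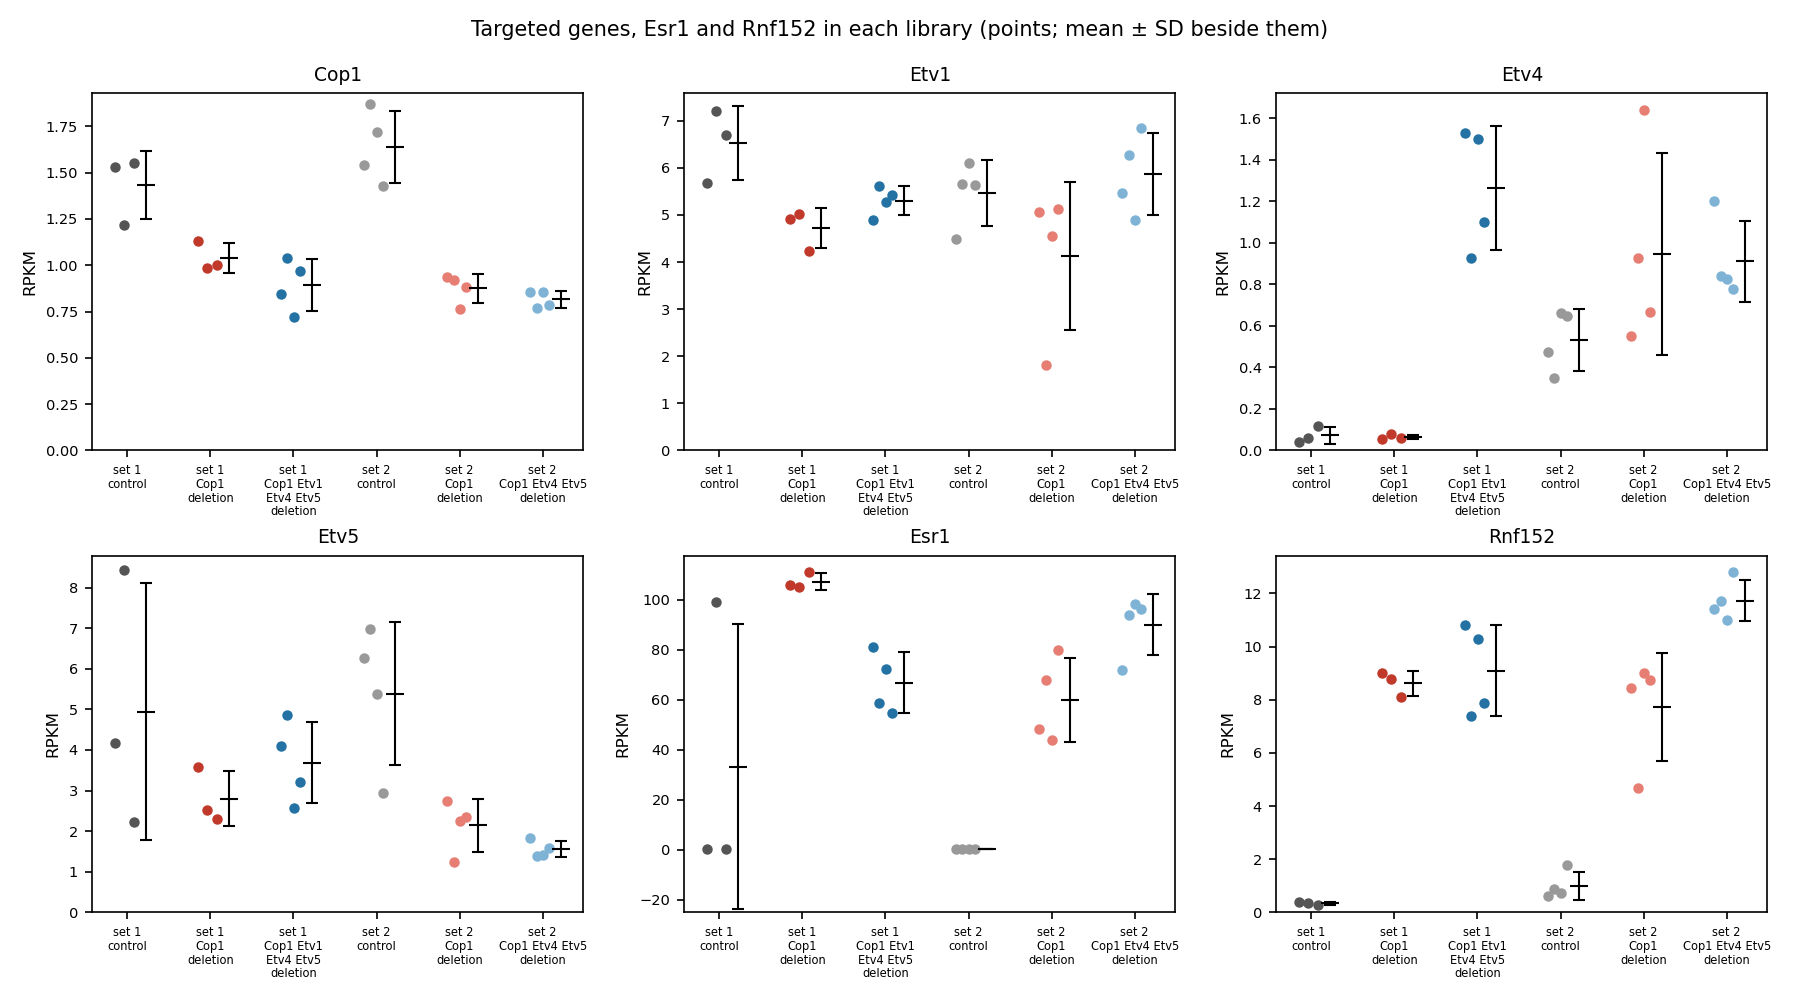
RPKM (vertical axes, linear) of Cop1, Etv1, Etv4, Etv5, Esr1 and Rnf152 in the 6 groups, with 1 point per library and mean ± SD beside the points. Cop1 reaches at most 1.13 RPKM in the libraries labelled with Cop1 deletion, Etv4 is highest in the libraries labelled Cop1 Etv1 Etv4 Etv5 deletion, and Esr1 reaches 99.1 RPKM in 1 set 1 control.

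After deletion of Cop1, 17 of 30 genes of β-cell identity and maturity fell and 4 rose, as measured by the mean of the 2 sets (7 control and 7 Cop1 deletion libraries). As a list they were not called with an estimated correlation (adjusted p = 0.57). Mafa, a transcription factor of mature β cells, fell by 2.80 log2 units (SE 0.23, adjusted p = 9.5e-08). Slc2a2, the glucose transporter GLUT2, fell by 2.68 (SE 0.19, adjusted p = 1e-08). Mafa was 218 ± 90 RPKM in control and 54 ± 11 after deletion in set 1 (n = 3 each), and 145 ± 34 and 11.5 ± 4.1 in set 2 (n = 4 each). Slc2a2 was 236 ± 42 and 58.9 ± 12 in set 1, and 64 ± 22 and 5.57 ± 1.5 in set 2. The largest rises were in Esr1 (log2 fold change 5.73, SE 0.74, adjusted p = 2e-05), Aqp3, a water and glycerol channel (5.06, SE 0.11, adjusted p = 6e-17), and Tm4sf20, a membrane protein gene (3.50, SE 0.22, adjusted p = 4e-09). Controls are labelled without Cre, and CreERT2 holds part of Esr1, so the rise of Esr1 cannot be read as an effect of Cop1 loss. Aqp3 went from 0.0807 ± 0.07 to 14.4 ± 2.4 RPKM in set 1 and from 0.241 ± 0.13 to 31.7 ± 1.7 in set 2.

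Of 30 genes of β-cell identity and maturity, 17 fell, 4 rose and 9 were not called (18 and 4 when adjusted over the list alone). Neurod1, an endocrine transcription factor, fell by 0.69 (SE 0.06, adjusted p = 1.9e-07), and Chgb, the granule protein chromogranin B, rose by 1.35 (SE 0.08, adjusted p = 2.8e-09). The list moved down in camera (adjusted p = 5.9e-05) and fry (adjusted p = 0.0016), but not in camera with an estimated correlation (adjusted p = 0.57). Among 23 genes of mitochondrial oxidation and shuttles, 11 fell, 1 rose and 11 were not called (13 and 1 over the list alone). These included Cox6a2, a subunit of cytochrome c oxidase (-2.13, SE 0.24, adjusted p = 5.2e-06), Gpd2, an enzyme of the glycerol phosphate shuttle (adjusted p = 0.00027), and Me1, malic enzyme (adjusted p = 0.0026). For this list the adjusted p was 0.003 in camera and 0.57 with an estimated correlation.

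Of 46 genes of the exocytosis machinery, 10 fell, 5 rose and 31 were not called (10 and 6 over the list alone), with no shift of the list (camera adjusted p = 0.22). Sytl4, which encodes the granule docking protein granuphilin, fell by 1.76 (SE 0.13, adjusted p = 1.4e-08). Of 29 ion channels of stimulus-secretion coupling, 7 fell, 4 rose and 18 were not called (9 and 5 over the list alone, camera adjusted p = 0.59). Trpm5, a calcium-activated cation channel, fell by 2.07 (SE 0.21, adjusted p = 1.5e-06), and Scn3a, a sodium channel, rose by 1.42 (adjusted p = 5.9e-06). Of 9 islet progenitor and dedifferentiation genes, 5 rose and none fell (5 over the list alone). Aldh1a3, a retinaldehyde dehydrogenase used as a marker of dedifferentiated β cells, rose by 3.01 (SE 0.43, adjusted p = 5.3e-05). Gast, the gastrin gene, rose by 1.08 (SE 0.17, adjusted p = 0.00014), and Neurog3, the endocrine progenitor factor, by 0.62 (SE 0.15, adjusted p = 0.0058). This list moved up in camera (adjusted p = 0.0036), with an adjusted p = 0.078 with an estimated correlation.

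Signalling genes moved in mixed directions. Of 17 FGF and ERK feedback genes linked to ETV factors, 3 rose, 2 fell and 12 were not called (3 and 2 over the list alone, camera adjusted p = 0.59). Dusp6, an ERK phosphatase, rose by 1.04 (SE 0.14, adjusted p = 2.3e-05), Dusp5 by 0.89 (adjusted p = 1.1e-06) and Spry2 by 0.69 (adjusted p = 4.1e-06), while Dusp4 fell by 0.68 (adjusted p = 0.0061). Of 15 PEA3-group targets named in other tissues, 3 rose, 1 fell and 11 were not called (camera adjusted p = 0.26). Spp1, which encodes osteopontin, rose by 1.69 (SE 0.35, adjusted p = 0.0019). Its value is uncertain, because NCBI Gene 100503439, which has no symbol here, had nearly the same values (2730 ± 780 RPKM against 2620 ± 810 for Spp1 in set 2 Cop1 deletion). Of 14 AP-1 and immediate early genes, which include known COP1 substrates, 4 fell and none rose (4 over the list alone). The AP-1 list had a camera adjusted p = 0.0056 and an adjusted p = 0.89 with an estimated correlation.

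Single markers of other cell types were called after Cop1 deletion. C1qa, a macrophage complement gene, was the 1 of 16 immune markers that rose (1.93, SE 0.12, adjusted p = 3e-09). The other C1q chain genes C1qb (0.43, adjusted p = 0.15) and C1qc (0.41, adjusted p = 0.14), chosen after their values were seen, were not called over both sets. In set 1 C1qb was 11.8 ± 1.1 RPKM in control and 11.8 ± 2.2 after deletion. In set 2 C1qb was called up, with log2 fold changes of 0.26 to 1.16 over the alternatives, and 10 of 35 alternatives ended that call. Of 11 ductal markers 3 rose, among them Krt7 by 0.80 (adjusted p = 7.9e-06), and none fell. The 24 acinar markers had a median log2 fold change of 0.95 with none called, and Ctrb1, a digestive enzyme of acinar cells, was 2500 ± 2200 RPKM in set 2 controls and 6260 ± 4600 after deletion. Camera put acinar (adjusted p = 0.003), immune (0.0056) and ductal (0.012) markers up, but not with an estimated correlation (adjusted p = 0.89, adjusted p = 0.89 and adjusted p = 0.57). Sst, the δ-cell hormone somatostatin, fell by 0.84 (SE 0.14, adjusted p = 0.00031), and Ppy, the hormone of PP cells, rose by 1.33 (adjusted p = 0.0016).

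In all, 1372 genes rose and 1505 fell after Cop1 deletion, 151 of them at least 2-fold. With libraries scaled to equal total RPKM, 1492 rose and 840 fell. No single library moved the count of called genes by more than 1.5 times. Cop1 itself fell by 0.48 (SE 0.07, adjusted p = 7.8e-05) and Etv5 by 0.85 (SE 0.23, adjusted p = 0.012).

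**Figure D2:**
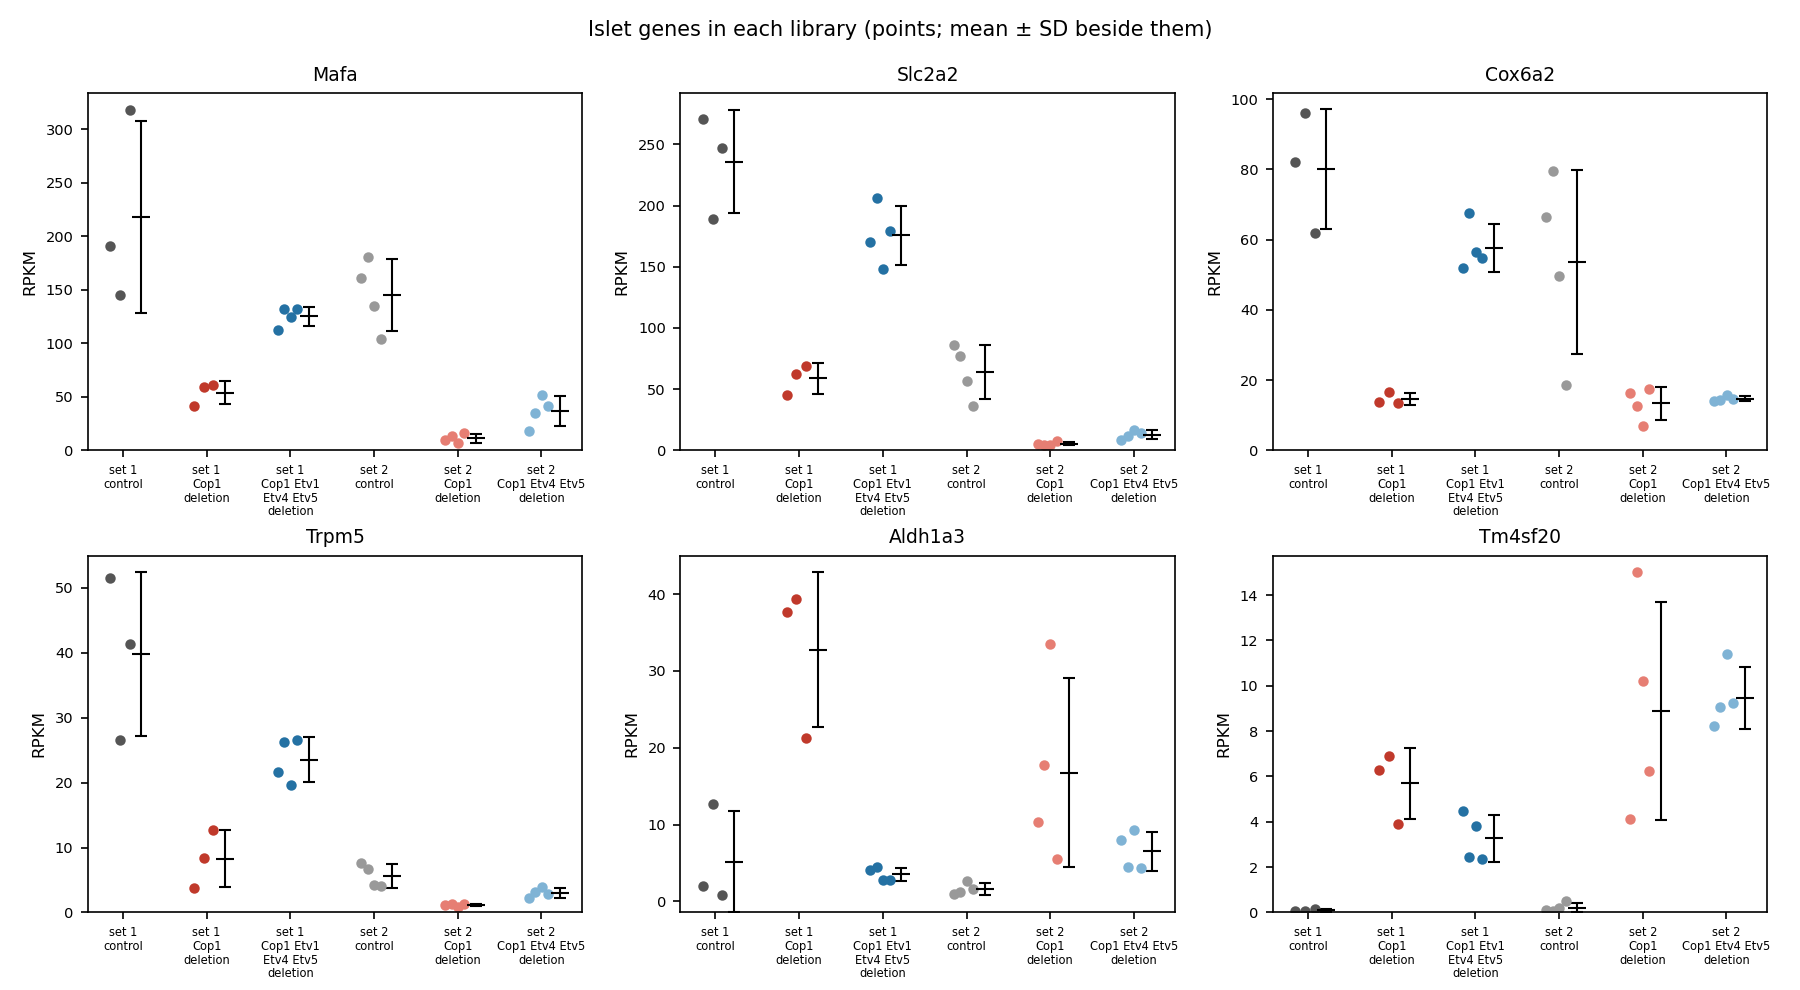
RPKM (vertical axes, linear) of Mafa, Slc2a2, Cox6a2, Trpm5, Aldh1a3 and Tm4sf20 in the 6 groups, with 1 point per library and mean ± SD beside the points. Slc2a2 averages 236, 58.9 and 176 RPKM across the set 1 groups and 64, 5.57 and 12.9 across the set 2 groups.

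Within set 1 (n = 3 each), Aqp3 rose by 4.67 (adjusted p = 5.9e-13), Rnf152, which encodes a lysosomal ubiquitin ligase, by 3.43 (adjusted p = 1.9e-08) and Tm4sf20 by 3.37 (adjusted p = 3.2e-06). Hunk, a protein kinase gene, rose by 2.52 (SE 0.15, adjusted p = 7.2e-09), from 0.522 ± 0.044 to 5.37 ± 0.37 RPKM. Slc2a2 fell by 2 (SE 0.28, adjusted p = 0.00012), Mafa by 1.95 (SE 0.35, adjusted p = 0.0011), Cox6a2 by 2.40 (SE 0.37, adjusted p = 0.00029) and Nnat, the imprinted gene neuronatin, by 2.44 (adjusted p = 4.1e-06). Of the 30 β-cell genes 11 fell, 3 rose and 16 were not called (17 and 3 over the list alone), with camera adjusted p = 0.00013 and adjusted p = 0.95 with an estimated correlation. Of 9 progenitor genes 3 rose (5 over the list alone), with camera adjusted p = 0.0075 and adjusted p = 0.1 with an estimated correlation. Among 22 genes of ER stress 4 rose, among them Pdia6, a protein folding enzyme (0.43, adjusted p = 0.004), with camera adjusted p = 0.016 and adjusted p = 0.95 with an estimated correlation. In set 2, 1 of them rose and 5 fell (camera adjusted p = 0.11), and over both sets 1 rose and 1 fell (camera adjusted p = 0.71). The list differed between the sets in camera (adjusted p = 0.00014) but not with an estimated correlation (adjusted p = 0.95).

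In set 1, 580 genes rose and 615 fell (1120 and 256 with libraries scaled to equal total RPKM). Cop1 itself was -0.33 (SE 0.11, adjusted p = 0.066) and passed without set 1 control replicate 2 (-0.41, adjusted p = 0.032). Esr1 rose by 4.91 (adjusted p = 0.0086), a call that was lost without set 1 control replicate 1 (adjusted p = 0.065) or replicate 3 (adjusted p = 0.056). The count of called genes was 718 without set 1 control replicate 1, 755 without set 1 Cop1 deletion replicate 2, 740 without set 1 Cop1 deletion replicate 3 and 1890 without set 2 Cop1 deletion replicate 2, which enters through the shared variance.

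Within set 2 (n = 4 each), Mafa fell by 3.65 (SE 0.3, adjusted p = 1.4e-07) and Slc2a2 by 3.37 (SE 0.24, adjusted p = 4.5e-08). Aqp3 rose by 5.45 (adjusted p = 2.3e-15) and Tm4sf20 by 3.62 (adjusted p = 1.1e-07). Among β-cell genes, 13 of 30 fell, 5 rose and 12 were not called (15 and 5 over the list alone), with camera adjusted p = 0.0015, fry adjusted p = 0.0089 and adjusted p = 0.71 with an estimated correlation. Of 23 mitochondrial genes 11 fell and 1 rose (the same over the list alone), with camera adjusted p = 0.0015 and adjusted p = 0.59 with an estimated correlation. In set 1, 4 of them fell and 1 rose, and that list was not called (camera adjusted p = 0.068). Beside these, 4 of 16 immune markers rose (8 over the list alone), C1qa by 2.56 (adjusted p = 6e-09), with camera adjusted p = 0.00014 and adjusted p = 0.71 with an estimated correlation. Of 11 ductal markers 4 rose, Krt7 by 1.32 (adjusted p = 8.5e-07). The acinar median was 1.42, with none of 24 markers called in limma and camera adjusted p = 0.0015 (adjusted p = 0.71 with an estimated correlation).

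Cop1 fell by 0.64 (adjusted p = 0.00011) in set 2 and Esr1 rose by 6.54 (adjusted p = 0.00013). Aldh1a3 rose by 2.83 (adjusted p = 0.0017), Dusp5 by 1.58 (adjusted p = 5.9e-08) and Etv5 fell by 1.13 (adjusted p = 0.012). Set 2 Cop1 deletion replicates 2 and 3, the 2 with Y-linked transcripts, lay apart on the second principal component (54.7 and 33.5, against -8.3 and 2 in the others of the group). Etv4/5 replicates 1 and 3, which also had Y-linked transcripts, did not lie apart in this way (-2 and -5.6, against -7 and -10.3). Keeping only Xist-positive libraries removes these outlying Cop1 deletion libraries together with the males, so the effects of the 2 cannot be told apart. With the Xist-positive libraries of set 2 alone, which leave 2 in the Cop1 deletion group, Aldh1a3 was 2.01 (adjusted p = 0.065) and Etv5 -0.90 (adjusted p = 0.17). The immune (camera adjusted p = 0.28), acinar (0.086) and ductal (0.057) lists were then not called. In all, 1303 genes rose and 1399 fell (840 and 1638 with libraries scaled to equal total RPKM), and 1321 genes were called with Xist-positive libraries alone. Exchanging the labels of set 2 control replicate 4 and set 2 Cop1 deletion replicate 1 gave 2931 called genes, more than the 2702 of the labels, so the count of set 2 alone does not exclude a chance division. Over the genes called in set 1, where set 2 labels enter only through the shared variance, these libraries scored with their own groups. The control was at -0.255 (controls -0.255 to -0.212) and the Cop1 deletion library at 0.101 (group 0.094 to 0.125).

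The 2 sets share no library, and most genes called in set 1 moved in the same direction in set 2. Of the 1195 genes called in set 1, 315 rose and 242 fell in both sets, where 52.7 and 60 would be expected of independent lists, and 21 were called in opposite directions. Of the genes called in set 1, 82.7% had the same sign in set 2, and the correlation of log2 fold changes over all genes was 0.47. The change differed between sets for 406 genes. C1qa rose more in set 2 (difference set 1 minus set 2 of -1.25, SE 0.24, adjusted p = 0.0071), as did Krt7 (-1.05, adjusted p = 0.0047). Hunk rose more in set 1 (1.62, SE 0.2, adjusted p = 0.00024). This count was 218 without set 1 control replicate 1, 239, 234 and 236 without set 1 Cop1 deletion replicates 2, 3 and 4, and 843 without set 2 control replicate 4.

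Adding the label of Etv1, Etv4 and Etv5 deletion to Cop1 deletion went with higher values of 8 of 30 β-cell genes and lower progenitor genes (set 1, n = 4 against n = 3). This comparison asks which effects of Cop1 loss need these factors. Slc2a2 rose by 1.58 (SE 0.26, adjusted p = 0.00089), from 58.9 ± 12 to 176 ± 24 RPKM, against 236 ± 42 in control. Ins1, the insulin 1 gene, rose by 0.90 (SE 0.13, adjusted p = 0.00017), from 24300 ± 4300 to 45100 ± 2100 RPKM, against 45600 ± 4900 in control. Aldh1a3 fell by 3.02 (SE 0.6, adjusted p = 0.0037), from 32.8 ± 10 to 3.53 ± 0.87, against 5.18 ± 6.6 in control. Neurog3 fell by 1.30 (SE 0.21, adjusted p = 0.00064) and Gast by 1.58 (SE 0.24, adjusted p = 0.00032).

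Of the 30 β-cell genes 8 rose, 3 fell and 19 were not called (9 and 4 over the list alone), without a shift of the list (camera adjusted p = 0.058, adjusted p = 0.93 with an estimated correlation). Other members that rose include G6pc2, an islet glucose-6-phosphatase (1.24, SE 0.22, adjusted p = 0.0014). Chgb fell by 1.61 (SE 0.12, adjusted p = 1.3e-07), from 2110 ± 44 to 699 ± 100 RPKM, against 745 ± 49 in control. Of 9 progenitor genes 3 fell and none rose (4 over the list alone). That list was called in camera (adjusted p = 0.0014), with an estimated correlation (adjusted p = 0.023) and in fry (adjusted p = 0.00017). Of 23 mitochondrial genes 2 rose, with Cox6a2 at 1.95 (SE 0.35, adjusted p = 0.0014), and none fell (camera adjusted p = 0.37). Of 17 FGF and ERK genes 2 rose, 1 fell and 14 were not called (camera adjusted p = 0.69). Of 14 AP-1 genes 3 rose, with Jund at 0.60 (adjusted p = 0.0023), and the list had camera adjusted p = 0.044 and adjusted p = 0.93 with an estimated correlation.

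Hunk fell by 2.31 (SE 0.14, adjusted p = 1e-08) to 0.685 ± 0.098 RPKM. Cartpt, a peptide hormone gene, fell by 2.28 (SE 0.26, adjusted p = 2.9e-05) and Meox1, a homeobox gene, by 2.06 (SE 0.27, adjusted p = 0.00011). Tacr3, the neurokinin 3 receptor gene, rose by 2.42 (SE 0.31, adjusted p = 7.2e-05). Cldn4, a tight junction gene, rose by 1.80 (SE 0.27, adjusted p = 3e-04), and Sst rose by 1.07 (SE 0.2, adjusted p = 0.0023). C1qa fell by 1.38 (SE 0.17, adjusted p = 5.3e-05), the 1 of 16 immune markers that was called, and the acinar median was -0.37 (camera adjusted p = 0.53). Of 24 acinar markers 1 was called, the protease gene Ctrc, at 13.5 ± 17 RPKM after Cop1 deletion and 96.3 ± 69 in the Etv1/4/5 libraries (3.27, SE 0.88, adjusted p = 0.031). That call ended without set 1 Cop1 deletion replicate 2 (adjusted p = 0.19) or 4 (0.13) and without Etv1/4/5 replicate 1 (0.074), 3 (0.098) or 4 (0.066). Etv4 rose by 1.63 (SE 0.19, adjusted p = 3.9e-05), against its label, and Cop1 was -0.15 (adjusted p = 0.5). In all, 523 genes rose and 386 fell (237 and 1390 with libraries scaled to equal total RPKM), and a fit of set 1 alone called 1704. The count was 594, 550 and 542 without set 1 Cop1 deletion replicates 2, 3 and 4, and 1516 without set 2 Cop1 deletion replicate 2.

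The Etv1/4/5 libraries were also compared with control (n = 4 against n = 3). The controls are those of the Cop1 deletion comparison. Aqp3 was higher by 5.02 (SE 0.15, adjusted p = 4.5e-14), at 18.6 ± 4.1 RPKM. Rnf152 was higher by 3.49 (SE 0.21, adjusted p = 5.8e-09), at 9.08 ± 1.7 RPKM against 0.346 ± 0.053. Tm4sf20 was higher by 2.65 (SE 0.32, adjusted p = 6.5e-05) and Tacr3 by 3.94 (SE 0.31, adjusted p = 2.1e-07). Meox1 was lower by -1.96 (SE 0.27, adjusted p = 0.00046). Ctrc was higher by 4.76 (SE 0.88, adjusted p = 0.007), at 96.3 ± 69 against 2.61 ± 1.5 RPKM, but not called without set 1 control replicate 3 (adjusted p = 0.053) or in a fit of set 1 alone (adjusted p = 0.061).

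The 1 β-cell gene of 30 that rose was Cltrn, the gene of the membrane protein collectrin (0.73, SE 0.13, adjusted p = 0.0039), with 1 up and 3 down over the list alone. The β-cell list was lower in camera (adjusted p = 0.0038) but not with an estimated correlation (adjusted p = 0.92). None of 9 progenitor genes and none of 22 ER stress genes was called in limma, although ER stress genes were higher as a list in camera (adjusted p = 5.7e-07), with adjusted p = 0.51 with an estimated correlation. Cop1 was lower by -0.48 (adjusted p = 0.019), with adjusted p = 0.12 and 0.11 without set 1 control replicates 1 and 3, and 0.066 and 0.082 without Etv1/4/5 replicates 1 and 3. In all, 129 genes rose and 60 fell. Without set 1 control replicate 2, the library with 99.1 RPKM of Esr1, 358 genes were called. The count was 91 and 123 without set 1 control replicates 1 and 3, 99 and 104 without Etv1/4/5 replicates 1 and 3, and 306 without set 2 Cop1 deletion replicate 2.

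In set 2, the Etv4/5 libraries were compared with the Cop1 deletion libraries (n = 4 each). Tacr3 rose by 1.98 (SE 0.29, adjusted p = 0.0049), from 2.05 ± 1.3 to 8.82 ± 1.9 RPKM. Chgb fell by 0.82 (SE 0.11, adjusted p = 0.004) and Dusp5 by 0.87 (SE 0.12, adjusted p = 0.004). Mafa rose by 1.60 (SE 0.3, adjusted p = 0.02), from 11.5 ± 4.1 to 36.5 ± 14 RPKM, against 145 ± 34 in control, and was not called without Etv4/5 replicate 2 (adjusted p = 0.07), 3 (0.073) or 4 (0.07). Ctrb1 was 6260 ± 4600 RPKM in the Cop1 deletion libraries and 1350 ± 680 in the Etv4/5 libraries.

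Of the 30 β-cell genes 4 rose, 1 fell and 25 were not called, with 15 up and 1 down when adjusted over the list alone. The β-cell list was up in camera (adjusted p = 5.2e-06), with adjusted p = 0.48 with an estimated correlation and fry adjusted p = 0.058. Beside it, 21 of 24 acinar markers were down over the list alone, with a median of -1.96 and camera adjusted p = 4.3e-10, and adjusted p = 0.48 with an estimated correlation. Over all genes, 1 acinar marker fell, the transcription factor gene Ptf1a (-1.44, SE 0.34, adjusted p = 0.038), which was not called with the acinar level as a covariate (adjusted p = 0.14) or without any 1 of the Etv4/5 libraries (adjusted p = 0.075, 0.098, 0.13 and 0.085). Of 11 ductal markers 5 were down over the list alone and 1 over all genes (camera adjusted p = 0.00043, adjusted p = 0.48 with an estimated correlation). None of 16 immune markers was called in limma over all genes, and that list was down in camera (adjusted p = 3.3e-05, adjusted p = 0.48 with an estimated correlation). The 17 hypoxia and culture stress genes (median -0.55, 1 called down, camera adjusted p = 0.00038) and 20 glucose-responsive and glycolytic genes (median -0.35, 8 down over the list alone, camera adjusted p = 5e-04) were lower too, but not with an estimated correlation (adjusted p = 0.51 and adjusted p = 0.48). Of 10 α-cell markers 5 were up over the list alone and 1 over all genes (camera adjusted p = 0.00021, adjusted p = 0.48 with an estimated correlation). None of 9 progenitor genes was called in limma, and Aldh1a3 was 16.8 ± 12 RPKM in Cop1 deletion and 6.54 ± 2.5 in Etv4/5 libraries.

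Cop1 was -0.06 (adjusted p = 0.7) and Etv5 -0.33 (adjusted p = 0.51), neither called. In all, 97 genes rose and 151 fell. A limma fit of set 2 alone called 0 genes (2077 at unadjusted p < 0.05), the acinar level as a covariate left 12, and the Xist-positive libraries alone left 7. The count was 15, 22 and 18 without Etv4/5 replicates 2, 3 and 4, 607 without set 2 control replicate 4, and 552, 83 and 767 without set 2 Cop1 deletion replicates 1, 2 and 4.

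Against the set 2 controls, which also serve the Cop1 deletion comparison, the Etv4/5 libraries had lower Slc2a2 and Mafa and higher Aqp3 and Tm4sf20 (n = 4 each). Slc2a2 was lower by -2.23 (SE 0.24, adjusted p = 8.9e-06), at 12.9 ± 3.7 RPKM against 64 ± 22, and Mafa by -2.05 (SE 0.3, adjusted p = 2e-04). Esr1 rose by 7.16 (SE 0.97, adjusted p = 1e-04), Aqp3 by 5.71 (SE 0.14, adjusted p = 9.9e-16) and Tm4sf20 by 3.85 (SE 0.29, adjusted p = 9.9e-08). Muc4, a mucin gene, rose by 2.66 (SE 0.3, adjusted p = 1.3e-05), from 2.56 ± 1.8 to 17.1 ± 3.7 RPKM.

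Among the β-cell genes 5 rose, 4 fell and 21 were not called (5 and 6 over the list alone, camera adjusted p = 0.62). Neurod1 fell by 0.50 (SE 0.08, adjusted p = 0.00036). Of 9 progenitor genes 2 rose (3 over the list alone), with Gast at 1.29 (SE 0.22, adjusted p = 0.00076) and camera adjusted p = 0.099. Of 17 hypoxia and culture stress genes 4 fell, with Vegfa, an angiogenic factor, at -0.49 (adjusted p = 0.0026), camera adjusted p = 0.00052 and adjusted p = 0.8 with an estimated correlation. C1qa was the 1 of 16 immune markers that rose (2.36, SE 0.16, adjusted p = 1.8e-08), and the acinar median was -0.56 with none of 24 called. Cop1 fell by 0.70 (adjusted p = 7.9e-05) and Etv5 by 1.46 (adjusted p = 0.0037). In all, 715 genes rose and 538 fell (430 and 777 with libraries scaled to equal total RPKM). The count was 801 without Etv4/5 replicate 2 and 1997 without set 2 Cop1 deletion replicate 2.

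The change from Cop1 deletion to added Etv deletion differed between the sets for 582 genes. Gast (-2.13, SE 0.32, adjusted p = 0.0014), Hunk (-2.15, SE 0.19, adjusted p = 7.5e-06), C1qa (-1.18, SE 0.23, adjusted p = 0.0077) and Chgb (-0.78, SE 0.16, adjusted p = 0.0096) went lower in set 1 than in set 2. Etv4 went higher (1.62, SE 0.27, adjusted p = 0.0024). Among 30 β-cell genes 3 differed, with a lower change in set 1 for Chgb and 2 others (camera adjusted p = 0.29). The acinar median differed by 1.63 in the same contrast (camera adjusted p = 0.0015, adjusted p = 0.84 with an estimated correlation). Genotype and set are not separable here, since no Etv genotype is in both sets. The count was 354, 312 and 301 without set 1 Cop1 deletion replicates 2, 3 and 4, 363 and 320 without Etv1/4/5 replicates 1 and 3, 310, 305 and 336 without Etv4/5 replicates 2, 3 and 4, and 985 without set 2 control replicate 4.

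The return toward control was then measured over whole lists taken from the other set. Over the 2702 genes called in set 2, the signed mean in set 1 was -0.358 ± 0.009 in control (n = 3), -0.121 ± 0.004 after Cop1 deletion (n = 3) and -0.267 ± 0.015 in the Etv1/4/5 libraries (n = 4). The Etv1/4/5 libraries thus lay 61.9% of the way back to control (exact permutation p = 0.0286, 2-sided, the smallest that 35 arrangements allow). Over the 1195 genes called in set 1, the signed mean in set 2 was -0.242 ± 0.02 in control, 0.108 ± 0.013 after Cop1 deletion and 0.069 ± 0.005 in the Etv4/5 libraries (n = 4 each). That return was 10.9% (exact permutation p = 0.0286, 2-sided, the smallest that 70 arrangements allow), but it was not called with libraries scaled to equal total RPKM (13.5%, exact permutation p = 0.229). Over the list called with the Y-linked covariate, an alternative chosen after the data were seen, it was 5.2% and not called either (exact permutation p = 0.0857). That covariate changed the gene list only, and the library values were not adjusted for it. The return of rising and falling genes was 54.2% and 70.4% in set 1 (exact permutation p = 0.0286 each), and 7.7% and 15.3% in set 2 (exact permutation p = 0.0571 each). The 2 returns rest on different gene lists.

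Of the genes that rose after Cop1 deletion in set 2, 185 were called down in the Etv1/4/5 libraries against the Cop1 deletion libraries of set 1, where 35.1 would be expected. Of those that fell, 170 were called up (51 expected). In the direction of Cop1 deletion, 27 of the rising and 7 of the falling genes moved further. In the reverse test, from set 1 to the Etv4/5 libraries, 19 and 12 genes were called back (6.1 and 4.2 expected) and 8 and 4 moved further.

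A group of genes stayed different from control under both added deletions, in comparisons that share no library. Between the Etv1/4/5 and Etv4/5 comparisons with control, 74 genes were up in both and 11 down in both, where 6.4 and 2.3 would be expected. Of these, 66 and 11 were also called in the 2-set Cop1 comparison, which shares their controls. Among them are Aqp3, Tm4sf20 and Rnf152, up, and Cop1, down. Of the 66, 10 were called down and 9 up in Etv1/4/5 against Cop1 deletion libraries, and none down and 4 up in Etv4/5 against Cop1 deletion libraries.

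**Figure D3:**
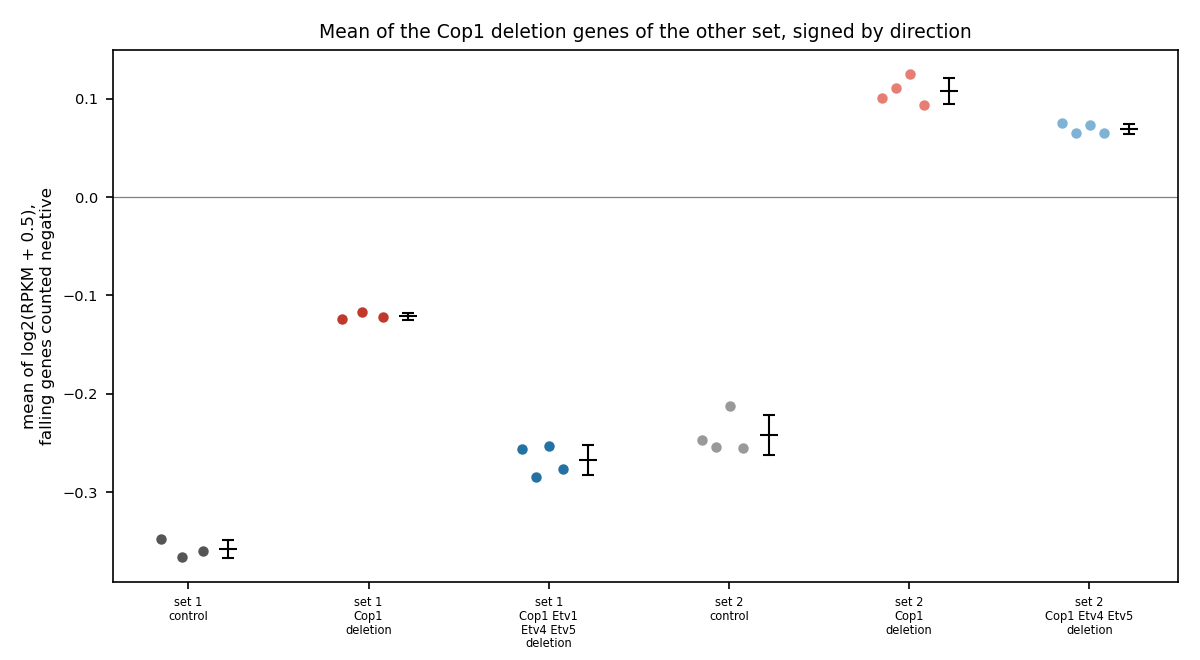
Mean of log2(RPKM + 0.5) over the genes called after Cop1 deletion in the other set, falling genes counted negative (vertical axis, log2 units), with 1 point per library and mean ± SD beside the points in the 6 groups. The Etv1/4/5 libraries average -0.267 between control at -0.358 and Cop1 deletion at -0.121, and the Etv4/5 libraries average 0.069 near Cop1 deletion at 0.108.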

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

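The tests in the next 3 paragraphs were chosen after their results were seen, except the returns and the common list, which were planned before, as were the differences between sets and between Etv deletions, the Dixon ratio and the regrouping of libraries.

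The library labelled set 1 control replicate 2 held 99.1 RPKM of Esr1, while the other 2 controls held 0.169 and 0.191. It is unlikely to be a Cop1 deletion library under a control label, since its signed mean over the set 2 genes lay at -5.2% of the way from the other 2 controls to Cop1 deletion (-0.366, against -0.124 in the lowest Cop1 deletion library). Admixture of RNA from a Cop1 deletion library is also argued against, since 73 genes that were higher than control under both Etv deletions, chosen without this library, reached a median of 14.6% of their Cop1 deletion level in it (upper quartile 43%), while Esr1 reached 92%. A CreERT2 transgene carried without loss of Cop1, the biological alternative, may account for the value, but Cop1 at 1.22 RPKM lay between the other 2 controls (1.53 and 1.55) and the highest Cop1 deletion library (1.13), so the test could not tell. The comparisons with set 1 controls keep this library, and without it 358 genes were called in the Etv1/4/5 libraries against control, where 189 were called with it.

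In all, 77 genes, 66 up and 11 down, differed from control under Cop1 deletion and under both added Etv deletions. CreERT2 itself, and not loss of Cop1, might change such genes. Chosen without the 1 control with Esr1, 99 genes lay in it at a median of 31.9% of the Cop1 deletion change (quartiles 5% and 52.7%). The other set 1 controls, left out in turn, gave -2% and 9.8%. Their gene choice and reference controls kept the library with Esr1, which can lower these values, so they are not like for like with 31.9%. Aqp3, Tm4sf20 and Rnf152 lay at 3%, -4.4% and 0.6% in the library with Esr1. The test cannot tell, since 1 library is too few. A linked variant or a transgene insertion on 1 chromosome is argued against for the group as a whole, since the genes lay on 19 chromosomes and the most frequent held 11.7% (9 of 77). Of these 9, 5 lie within 10 megabases of Etv4. They were also called after Cop1 deletion in libraries without an Etv4 deletion label, and linkage to Etv4 cannot account for that call. Linkage stays open for their change under the Etv deletions. Tm4sf20 (3.50 after Cop1 deletion over both sets), Rnf152 (2.95) and Gm17634 (2.07) lie on chromosome 1, as does Cop1. A count over chromosomes does not test linkage for these genes. The controls are floxed for Cop1 too, so a variant carried with the floxed allele would not by itself separate the groups. A transgene insertion on that chromosome stays open. An effect of COP1 that does not pass through these ETV factors is the biological alternative and was not tested further.

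The return toward control was 61.9% (SD 6.5) in set 1 and 10.9% (SD 3.8) in set 2. The SD beside a return is the larger SD of the Cop1 deletion and Etv deletion libraries, as a percentage of the difference between Cop1 deletion and control. It leaves out the spread of the controls (0.02 in set 2, against 0.013 and 0.005 in the other groups), so it is not the uncertainty of the return itself. Unequal spread of males and females over set 2 could lower its return. With Xist-positive libraries of set 2 alone the return was 10.1% (SD 2.5), so it did not rise toward that of set 1. That value rests on the 1742 genes then called in set 1, not on the 1195 of the main list. The filter also removes the outlying Cop1 deletion libraries, so the effect of sex cannot be told apart from theirs. In addition, 2 libraries against 2 are too few for a test of that return itself (exact permutation p = 0.333, the smallest possible). The 2 gene lists differ, and over 1 common list the returns were 64.9% (SD 4.5) and 30.7% (SD 17.9), but that list was chosen with the libraries in which it is measured, so the test cannot tell and a difference in lists may remain. A difference between the sets other than the Etv genotype cannot be told apart, since 582 genes changed differently and no Etv genotype is in both sets. The biological alternative, that loss of Etv1 or of the last Etv4 allele adds to the return, meets the same limit.

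The change after Cop1 deletion differed between the sets (set 1 minus set 2), by a test of the difference, in 406 genes. Among them were Nnat (-1.51, SE 0.33, adjusted p = 0.017), C1qa (-1.25, SE 0.24, adjusted p = 0.0071), Hunk (1.62, SE 0.2, adjusted p = 0.00024) and Gm15663, a gene model without a known function (1.44, SE 0.21, adjusted p = 0.0013). Nnat was not called without set 1 control replicate 1 (adjusted p = 0.067).

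The change from Cop1 deletion to added Etv deletion differed between the sets, by the same kind of test, in 582 genes. The log2 change was higher in set 1 for Etv4 (1.62, SE 0.27, adjusted p = 0.0024), Cox6a2 (1.74, SE 0.47, adjusted p = 0.043), Nnat (1.41, SE 0.32, adjusted p = 0.018) and Sst (1.13, SE 0.27, adjusted p = 0.025). It was lower in set 1 for Chgb (-0.78, SE 0.16, adjusted p = 0.0096), C1qa (-1.18, SE 0.23, adjusted p = 0.0077), Hunk (-2.15, SE 0.19, adjusted p = 7.5e-06) and Gm15663 (-2.35, SE 0.21, adjusted p = 7.5e-06). Further genes with a lower change in set 1 were Gast (-2.13, SE 0.32, adjusted p = 0.0014), Neurog3 (-1.04, SE 0.29, adjusted p = 0.046), Meox1 (-1.35, SE 0.37, adjusted p = 0.048) and Muc4 (-1.88, SE 0.44, adjusted p = 0.023). Leaving out single libraries ended the call of Cox6a2 (adjusted p up to 0.11), Neurog3 (up to 0.15), Meox1 (up to 0.12), Sst (up to 0.07) and Muc4 (up to 0.06).

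Single libraries far from the other 3 of their group were looked for with the Dixon ratio in 156 groups of 4 values, and 12 passed, where chance passes about 1 in 20. Set 2 Cop1 deletion replicate 2 was low in Etv1 (1.81 RPKM, others 4.56 to 5.12), Rnf152 (4.68, others 8.44 to 9.02) and Gm15663 (7.16, others 9.55 to 9.91). Set 2 Cop1 deletion replicate 3 was low in Aqp3 (29.1, others 32.2 to 32.7) and high in Hspa1a, a heat shock gene (3.13, others 0.377 to 0.496). Set 2 control replicate 4 was high in Hspa1a (10.4, others 0.449 to 0.806) and in Dnajb1, another heat shock gene (30.9, others 17.9 to 18.9), and low in Gm15663 (2.49, others 4.13 to 4.43). Etv4/5 replicate 1 was low in Esr1 (71.9, others 93.9 to 98.3) and Ins1 (25000, others 28300 to 28500). Etv4/5 replicate 3 was high in Cox6a2 (15.8, others 14.2 to 14.5) and in the insulin share of RPKM (28.9%, others 25.8% to 26%).

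Regrouping the libraries into other splits of the same sizes asked whether a chance division calls as many genes. For Cop1 deletion over both sets, 1 of 100 splits, the real one, reached its count of 2877, and the highest other reached 1176, so a chance division is argued against. In set 2 it cannot be excluded by the count alone, since 2 of 35 splits reached the real 2702, with the other at 2931. That other split exchanges set 2 control replicate 4 and set 2 Cop1 deletion replicate 1, which scored with their own groups over the set 1 genes (-0.255 and 0.101). Cop1 ran from 1.43 to 1.87 RPKM in the set 2 controls and from 0.763 to 0.934 in the Cop1 deletion libraries, so exchanged labels are argued against. In set 1 the 10 splits are too few to tell, with 1195 for the real split and 2 for the highest other. Only the real split reached its count for Etv1/4/5 against Cop1 deletion (1 of 35, real 909, highest other 2) and against control (1 of 35, real 189, highest other 30). The same held for Etv4/5 against Cop1 deletion (1 of 35, real 248, highest other 3) and against control (1 of 35, real 1253, highest other 3). It also held for the difference between the Etv deletions (1 of 100, real 582, highest other 249). These shares are under the planned limit of 5 in 100. They are the smallest that the splits allow, and the 9 comparisons were not corrected for their number. For the comparisons other than the difference, a chance division is thus argued against but not excluded. For Etv4/5 against Cop1 deletion, a fit of set 2 alone called 0 genes, the acinar covariate left 12 and the Xist-positive libraries alone left 7. Without Etv4/5 replicates 2, 3 and 4 in turn, 15, 22 and 18 were called. For the difference between the sets, 4 of 100 splits reached the real 406, with the highest other at 645, which is under the planned limit of 5 in 100. For both differences, the splits mixed the labels within each set, which removes the deletion effect itself. A split that keeps 1 set near its labels turns the contrast into the effect in that set. The shares for the differences therefore cannot tell whether equal effects in both sets would give as many genes.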

How the results depend on the processing

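The 3 alternatives named as chosen after seeing the data are marked here as added, and all others were planned before. Of 423 named gene results, 258 kept their direction and call in every alternative that gave a value for them. Leaving out 1 library kept 8578 of 9298 gene results, weakened 704, strengthened 11 and reversed 5. Camera calls of lists were weaker with an estimated correlation in 42 of 43 cases. No paired analysis was possible because replicates are numbered in accession order only. The planned fit without the libraries that share a sample number is the fit reported, so it gives no further value, and differences across sets have no value in a fit within a set. The cause of the changes below was not tested, except that a fold minimum calls fewer genes by construction. Relative depth in set 1 was a median of 0.382 against 0.878 in set 2, which limits small changes of low genes there.

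Counts are given in the order Cop1 deletion over both sets, set 1, set 2, Etv1/4/5 against Cop1 deletion, Etv1/4/5 against control, Etv4/5 against Cop1 deletion, Etv4/5 against control, difference between sets and difference between Etv deletions. With at least a 2-fold change they were 151, 183, 235, 124, 47, 30, 132, 116 and 131. Array weights raised all of them, to 6259, 5429, 5035, 3712, 3022, 3217, 4766, 3872 and 3737. Leaving out 1 library gave 2272 to 3393, 718 to 1890, 1933 to 3411, 542 to 1516, 91 to 358, 15 to 767, 801 to 1997, 218 to 843 and 301 to 985. The returns then ran from 56.6% to 63.2% in set 1 and from 8.3% to 12.5% in set 2.

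A fit within the set called 2112 genes for Cop1 deletion in set 1, 1469 in set 2, 1704 for Etv1/4/5 and 0 for Etv4/5 against Cop1 deletion (limma, 2077 at unadjusted p < 0.05), and 664 for Etv4/5 against control. With Xist-positive libraries of set 2 alone (added), the counts were 1321 for Cop1 deletion in set 2, 1421 for Etv1/4/5 and 7 for Etv4/5 against Cop1 deletion (1432 at unadjusted p < 0.05), 267 for the difference between sets and 301 between Etv deletions. For Etv4/5 against Cop1 deletion, the Y-linked covariate (added) gave 455 and the acinar covariate (added) 12. The planned fit without set 1 control replicate 2, singled out after its Esr1 value was seen, gave 358 for Etv1/4/5 against control.

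Scaling libraries to equal total RPKM gave 1627 for Etv1/4/5 against Cop1 deletion and 613 for the difference between sets. It also moved the balance of directions. The share of called genes that rose went from 47.7% to 64% over both sets, from 48.5% to 81.4% in set 1, from 48.2% to 33.9% in set 2, from 57.5% to 14.6% for Etv1/4/5 against Cop1 deletion, from 57.1% to 35.6% for Etv4/5 against control, from 35.2% to 86.6% for the difference between sets and from 57.7% to 18% between Etv deletions. Quantile normalization moved it from 39.1% to 49.3% for Etv4/5 against Cop1 deletion. The median log2 fold change under equal totals was 0.117 in set 1, -0.131 for Etv1/4/5 against Cop1 deletion, 0.2 for the difference between sets and -0.135 between Etv deletions. The counts of rising and falling genes thus depend on whether totals are made equal. With median-of-ratios rescaling the share stayed near that of the main fit. It was 50.6% over both sets, 50.6% in set 1, 50.8% in set 2 and 55% for Etv1/4/5 against Cop1 deletion. For Etv4/5 against control it was 55.7%, for the difference between sets 37.7% and between Etv deletions 59.2%. The return in set 2 was 13.5% under equal totals (exact permutation p = 0.229) and was no longer called. Over the list called with the Y-linked covariate it was 5.2% (exact permutation p = 0.0857) and not called either, but the covariate changed only the list and not the library values.

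Reversed directions concerned Etv4 and Etv5, in comparisons where they were not called, and 1 list. Etv4 in Etv4/5 against Cop1 deletion was 0 with a pseudocount of 1, -0.01 with median-of-ratios rescaling, -0.01 with quantile normalization and 0 with the Y-linked covariate, and without single libraries it ran from -0.12 to 0.22, with -0.07 and -0.08 without set 2 Cop1 deletion replicate 4 and Etv4/5 replicate 1. Etv4 after Cop1 deletion in set 1 was 0.06 with array weights and ran from -0.06 to 0.04 without single libraries. Etv5 in Etv1/4/5 against control ran from -0.66 to 0.2 without single libraries. The list of genes disallowed in β cells reversed in camera for Etv4/5 against Cop1 deletion with array weights (adjusted p = 0.96) and with Xist-positive libraries (adjusted p = 0.0094), and for Cop1 deletion in set 2 with Xist-positive libraries (adjusted p = 0.3).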

Other observations

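The list tests of this paragraph were planned, and the tests of the paragraph on genes near Etv4 were chosen after their result was seen. Over both sets (n = 7 each), of 8 δ, PP and ε-cell markers 2 rose, 2 fell and 4 were not called after Cop1 deletion (the same over the list alone, camera adjusted p = 0.89). Pyy, a gut and islet peptide, rose by 1.06 (adjusted p = 0.00031) and Ghsr, the ghrelin receptor gene, fell by 0.61 (adjusted p = 6e-04). Of 37 genes of G-protein signalling of insulin release, 4 rose, 6 fell and 27 were not called (camera adjusted p = 0.7), and Ffar2, a receptor for short-chain fatty acids, rose by 0.99 (adjusted p = 1.2e-07). Plk2, a polo-like kinase gene, rose by 0.98 (adjusted p = 2e-06) and was the 1 called gene of 16 p53 targets. Of 17 COP1 ligase partners and substrates, 3 rose, 2 fell and 12 were not called (camera adjusted p = 0.59), with Trib1, a COP1 adaptor, up by 0.58 (adjusted p = 0.00015) and Ets2, an ETS factor, which fell by 0.38 (adjusted p = 0.0052).

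Meox1 lies near Etv4 in GRCm38.p6. Within 10 megabases of Etv4, 255 genes were tested, and 11 were called in the Etv1/4/5 libraries against control, where 3.4 would be expected (odds ratio 3.52, 95% interval 1.7 to 6.57, Fisher exact p = 0.00057, 2-sided). In Etv1/4/5 against Cop1 deletion 24 were called (16.2 expected, Fisher exact p = 0.051). In Etv4/5 against control 27 were called (22.3 expected, Fisher exact p = 0.31), and in Etv4/5 against Cop1 deletion 5 were called (4.4 expected, Fisher exact p = 0.63).

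Dnajb1, a heat shock gene chosen after its values were seen, was at 1050 ± 330 RPKM (n = 3) in set 1 controls and 21.5 ± 6.3 (n = 4) in set 2 controls, a difference that was not tested. The first principal component held 67.6% of the variance and separated the sets. On the third, set 2 control replicate 4 lay at 43.6, and the other set 2 controls at 4.9 to 9.5. A gene without a symbol reached a mean of 36972 RPKM, and genes without a symbol held 8.9% to 15.8% of RPKM per library.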
